A study of Mus musculus with 6 samples.

How the data were processed

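RNA from mouse liver at 39 weeks of age (C3H/HeNCrlBR background, per the labels) was compared on 6 Agilent 2-colour oligonucleotide arrays, with Cy3-labelled cRNA on the green channel and Cy5-labelled cRNA on the red channel. All animals had received diethylnitrosamine (DEN), a carcinogen that initiates liver tumours, and all but the mice of 1 CAR-KO group also received phenobarbital (PB), a tumour promoter given in the drinking water. The arrays formed 3 pairs of 2 arrays with the dyes swapped within each pair. The pairs compared wild-type (WT) with CAR-knockout (CAR-KO) liver after DEN and PB, CAR-KO liver after DEN and PB with CAR-KO liver after DEN alone, and WT tumour with CAR-KO liver after DEN and PB. CAR is the nuclear receptor encoded by Nr1i3.

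Each deposited scanner file gives mean signals and local background medians per spot, which are the authors' scanner readings in intensity units without normalization. The same files hold processed intensity values that the authors made with Agilent Feature Extraction, with background subtraction and dye normalization. The deposited ratio column is a log10 ratio of red over green processed signal, and the deposited value table is the same log10 ratio, with a largest difference of 0 between them. The deposited p-value column is the software's error model for 1 spot on 1 array. Deposited columns of other kinds are spot flags (saturation, non-uniformity, signal well above background, control type). Per the file headers, Feature Extraction 7.1.1 read 5 of the arrays and 7.5.1 read array 2 of the tumour pair, while the submitters' notes name 7.5 for all 6.

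Median signals per array ran from 186.5 to 493.5 in Cy3 and from 129.4 to 417.9 in Cy5. Median local background was 53 to 61 (Cy3) and 60 to 62 (Cy5) on 5 arrays, and 288 (Cy3) and 299 (Cy5) on array 2 of the tumour pair, which came from a different scanner. Between 84.25% and 98.65% of spots per channel were well above background, between 9 and 30 spots per array were saturated, and between 6 and 55 spots per array carried an outlier flag and were set to missing. The number of arrays limits the precision. A batch term for the different scanner could not be separated from that array, since the batch held 1 array.

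The arrays carried 22393 spots, of which 1075 were controls. Spots of the same probe were averaged, giving 20868 probes. The reference table gave a single gene symbol to 9688 probes (9544 genes), of which 8947 were matched by accession, 377 by a symbol in the probe description and 364 by an older symbol. The other 11180 probes had no symbol and were counted as probes only. No genome build was named in the files, so no positions are given.

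Signals were corrected with normexp (offset 50) and normalized by loess within each array, and log2 ratios were fitted with limma (lmFit and eBayes) on all 6 arrays together, with 3 contrasts and a dye effect per probe. This left 2 residual degrees of freedom per probe, to which the moderated variance added 5.48 prior degrees of freedom. WT tumour was compared with WT liver indirectly, as the difference between the ratios of each to CAR-KO liver. A probe was tested when at least 1 channel was well above background on at least 2 arrays, which held for 20744 probes. Probes were called at a Benjamini-Hochberg adjusted p under 0.05 over all probes tested, 2-sided. The labels do not say whether both arrays of a pair held the same RNA extracts, so the p-values measure the spread between dye-swapped arrays, which can be technical only. SE values are limma's standard errors of the log2 ratio, with 2 arrays per direct comparison.

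The comparisons, the gene lists, the naming rule and the first set of alternatives were fixed before the data were examined. Named genes were the 10 with the largest increase and the 10 with the largest decrease per comparison among called probes with the same sign on both arrays and a signal well above background on both. Added to these were Nr1i3 and Tuba8 in every comparison, the 10 with the largest values in both WT liver and WT tumour, and up to 4 called members of each list with a list call or at least 3 called members, and list members given for contrast. A gene with several probes was represented by its brightest probe.

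The 27 lists covered CAR and PB responsive drug metabolism, NRF2 antioxidant genes, bile acid synthesis and transport, lipogenesis, cholesterol synthesis, fatty acid oxidation, gluconeogenesis and amino acid catabolism, pericentral and beta-catenin target genes, periportal genes, cell cycle, p53 targets, liver tumour and fetal liver markers, tubulins, acute phase response, interferon response, male-biased and female-biased liver genes, and markers of hepatocytes, cholangiocytes, stellate cells, endothelium, macrophages, lymphocytes, neutrophils, erythroid cells, pancreatic acini and adipocytes. Each list was tested in the 4 comparisons with camera (preset correlation 0.01) on 1 probe per gene, with Benjamini-Hochberg adjustment over the 108 tests. The tests were repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction. With an estimated correlation camera rests on the 2 residual degrees of freedom, so its p-values rise even where the estimate is near the preset. For a list whose estimate is near the preset, a call lost in that setting therefore does not show that correlation between genes had made it. Estimates ran from -0.113 (neutrophil markers) to 0.55 (pancreatic acinar markers), with 0.263 for the acute phase list and 0.171 for the female-biased list. Where the estimate is well above the preset, that setting cannot separate correlation from the few degrees of freedom. After adjustment many lists share the value 0.259 there. Members were also counted as adjusted over the list alone.

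The procedure was tested on simulated data in which 200 of 20744 probes were changed. With a true log2 ratio of 0.5, 0 of 200 were recovered, beside 2 false calls in each of the comparisons simulated. With a true log2 ratio of 1 the procedure recovered 92% (WT against CAR-KO liver, 184 probes beside 18 false calls) and 86.5% (WT tumour against CAR-KO liver, 173 beside 11). With a true log2 ratio of 2 all 200 were recovered, beside 30 and 16 false calls. Alternatives were other background and normalization choices, other filters, no dye effect, fits on the arrays of a pair alone, array weights, the software's own error model, a 2-fold threshold, and leaving out each array in turn. R 4.3.3, limma 3.58.1, data.table (1.17.8) and jsonlite 2.0.0 were used.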

Results

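The series measured gene expression on 6 arrays, as 3 dye-swapped pairs of 2 arrays each, to find genes that depend on CAR and are induced during liver tumour development. Each pair set liver or tumour RNA of DEN-treated mice against another such RNA on the same arrays. Tuba8, an alpha-tubulin gene, is the gene that the study took further. Median local background was 53 to 62 on 5 arrays and 288 (Cy3) and 299 (Cy5) on array 2 of the tumour pair, whose median signals were 493.5 and 417.9.

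Nr1i3, the gene deleted in the CAR-KO mice, had a log2 ratio of WT over CAR-KO liver of 0.79 ± 0.16 (SE; 1.08 and 0.49 on the 2 arrays), which did not pass the test (limma adjusted p = 0.412). In WT tumour over CAR-KO liver its log2 ratio was 1.81 ± 0.16 (1.71 and 1.90 on the 2 arrays, adjusted p = 0.00194). In CAR-KO liver after DEN and PB over DEN alone it was 0.19 ± 0.16. The files do not say where the Nr1i3 probe lies relative to the deleted part of the gene, so these values check nothing about the genotypes. The WT liver value passed with array weights (adjusted p = 0.0307) and without either tumour array (adjusted p = 0.029), and its adjusted p ran from 0.029 to 1 over 17 alternatives, with a log2 ratio of 0.60 to 1.17.

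The comparison of WT with CAR-KO liver asked which genes depended on CAR in liver treated with DEN and PB. Cytochrome P450 genes of drug metabolism were far higher with CAR present. Cyp2b9 was 27.1-fold higher (log2 ratio 4.76 ± 0.20, adjusted p = 0.000382), Cyp2b13 12.2-fold (3.62 ± 0.18) and Cyp2c37 9.09-fold (3.19 ± 0.15), and Cyp2b10, the classical PB-induced gene of mouse liver, had a log2 ratio of 1.89 ± 0.16 (adjusted p = 0.00746). Ly6d, a gene for a membrane-anchored surface protein, was 11.9-fold higher (3.58 ± 0.17), and Tnnc2, a fast skeletal muscle troponin, was lower (-1.78 ± 0.15, adjusted p = 0.00746). In all, 19 probes were higher and 2 were lower, of 20743 tested, and 471 passed an unadjusted p under 0.05, where chance alone gives 1037. A count under that of chance means that the p-values ran large, so probes that missed the threshold cannot be taken as unchanged. With array weights, 1.77 on the arrays of this pair and 0.486 on the tumour arrays, the count was 1409.

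Of the 21 measured members of the CAR and PB drug metabolism list, 9 were higher and 0 lower over all probes, 19 were higher when adjusted over the list alone, and all 21 ratios were positive, with a median log2 ratio of 1.66. Besides the genes above, Cyp2c55 (2.67 ± 0.15), Gstm2 (2.34 ± 0.19), Cyp2c29 (2.29 ± 0.16), Sult1e1 (1.77 ± 0.18) and Por (1.66 ± 0.17), which encodes the reductase that passes electrons to microsomal P450 enzymes, were members that passed the test. Camera called the list higher (adjusted p = 9.33e-69), with an adjusted p = 0.259 with an estimated correlation and an adjusted p = 0.0462 with fry. The estimated correlation was 0.014, near the preset 0.01, while the unadjusted camera p went from 8.64e-71 to 0.00329. Cyp2c39 (2.75 ± 0.19), Pnliprp1 (2.35 ± 0.15), a pancreatic lipase-related gene, and the ammonium transporter gene Rhbg (2.17 ± 0.17) were also higher. Ly6c1 (1.29 ± 0.16, adjusted p = 0.0497), outside the naming rule and chosen after its value was seen, completed the 15 named genes.

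Genes marking the pericentral zone of the liver lobule, many of them targets of beta-catenin, also leaned higher in WT liver. Of 14 measured members, Rhbg and Nkd1 (1.48 ± 0.16, adjusted p = 0.0228), an inhibitor of Wnt signalling, passed the test, 7 were higher when adjusted over the list alone and 12 ratios were positive (median 0.55). Glutamine synthetase (Glul) had a ratio of 1.77 ± 0.24 that missed the threshold (adjusted p = 0.0906). Of 7 measured periportal genes, Etnppl was lower (-1.35 ± 0.16, 2.55-fold, adjusted p = 0.0497) and 6 ratios were negative (median -0.48). The NRF2 list (13 measured, median 0.20) was called higher and the list of gluconeogenesis and amino acid catabolism (11 measured, median -0.29) lower by camera with 0 members passing limma's test (adjusted p = 4.48e-05 and 2.97e-05; each adjusted p = 0.259 with an estimated correlation). Camera called the pericentral list higher (adjusted p = 2.05e-18) and the periportal list lower (adjusted p = 8.68e-05), each with an adjusted p = 0.259 with an estimated correlation. Cyp2b9 and Cyp2b13 were also the 2 called members among 9 measured female-biased liver genes (median 0.24), and Ly6d the only called member of 15 tumour and fetal liver markers (median 0.28). Camera called both lists higher (adjusted p = 2.99e-09 and 9.01e-07), each with an adjusted p = 0.259 with an estimated correlation.

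Tuba8 had a log2 ratio of 1.40 ± 0.20 in WT over CAR-KO liver (1.14 and 1.67 on the 2 arrays), 2.65-fold, and did not pass the test over all probes (limma adjusted p = 0.104). It passed in fits on the arrays of this pair alone (adjusted p = 0.0012), with array weights (adjusted p = 0.00241) and without either tumour array (adjusted p = 0.000269), with a range of 0.000269 to 1 over 15 alternatives. Its probe was dim, and its ratio was positive in all 15, from 0.92 without background subtraction to 3.75 on the signals processed by the Agilent software. Of 11 measured tubulin genes 0 passed over all probes and 2 passed when adjusted over the list alone. Camera called the tubulin list higher (adjusted p = 3.45e-05, median 0.17), with an adjusted p = 0.259 with an estimated correlation and an adjusted p = 0.0545 without array 2 of the pair.

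The muscle gene Tnnc2 had a log2 ratio of -1.78 in WT over CAR-KO liver, 1.78 in CAR-KO liver with PB over DEN alone and -1.83 in WT tumour over CAR-KO liver. The 9 probes described as skeletal muscle sarcomere genes, chosen because they were lower in WT tumour, had medians of -0.96, 0.99 and -1.49 in those comparisons. Of these only Tnnc2 passed in WT liver and 0 with PB. Over 27 measured muscle markers not looked at before the medians were -0.048, 0.045 and -0.038. Of the 27, limma called 0 in the first 2 comparisons, while in WT tumour Mylpf, Tnni2 and Sln were lower and Smpx was higher (0.85 ± 0.16, adjusted p = 0.0327). Sln, not among the 9, had ratios of -0.10, -0.26 and -0.79. Markers of pancreatic acini had 0 members passing the test, with 6 of 7 ratios negative in WT over CAR-KO liver (median -0.18) and 7 of 7 positive with PB in CAR-KO liver (median 0.27). Camera called that list lower in the first comparison (adjusted p = 0.00187; adjusted p = 0.424 with an estimated correlation) and higher in the second (adjusted p = 0.000108; adjusted p = 0.372 with an estimated correlation). The first call was lost without array 1 of its pair (adjusted p = 0.108) and the second without array 2 of its pair (adjusted p = 0.15).

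The 19 probes higher in WT liver became 5 or 4 without array 1 or 2 of the pair, 8 without either array of the PB pair and 76 without either tumour array, and the 2 lower became 0, 0 and 18, while Cyp2b9, Cyp2b13, Ly6d and Cyp2c37 passed without any single array. On the signals processed by the Agilent software 0 probes passed (smallest adjusted p = 0.185), though all 21 kept their sign.

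The comparison of CAR-KO liver after DEN and PB with DEN alone asked what PB did without CAR. With 0 probes of any kind passing the test here, the P450 genes that were higher with CAR present did not pass either. Cyp2b10 had a log2 ratio of 0.01 ± 0.16, Cyp2b13 0.10 ± 0.18, Cyp2c37 0.08 ± 0.15, Cyp2c55 0.06 ± 0.15, Cyp2b9 0.28 ± 0.20, Cyp2c29 0.28 ± 0.16 and Cyp2c39 0.51 ± 0.19 (-0.01 and 1.03 on the 2 arrays). Tuba8 had a log2 ratio of -0.03 ± 0.20. The ratio of Cyp3a11, a P450 gene that PB also induces through the receptor PXR, was 1.42 ± 0.21 (0.73 and 2.11 on the 2 arrays), which did not pass over all probes.

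With limma 0 probes were higher and 0 lower, 565 passed an unadjusted p under 0.05 where chance alone gives 1037, and the smallest adjusted p was 0.0937, for Tnnc2. The p-values thus ran large here too, and the fit pools the spread of all 3 pairs. The count of 0 is therefore no evidence that PB changed nothing without CAR. With array weights 889 probes passed an unadjusted p under 0.05. The CAR and PB list had 17 of 21 positive ratios (median 0.10) and 1 member passing when adjusted over the list alone. Camera called it higher (adjusted p = 0.000183), with an adjusted p = 0.259 with an estimated correlation. Besides the pancreatic acinar list given above, camera called 4 further lists higher with 0 members passing limma's test. These were the NRF2 list (adjusted p = 0.0238, median 0.12; adjusted p = 0.313 with an estimated correlation), the stellate cell list (adjusted p = 0.0238, median 0.16; adjusted p = 0.313 with an estimated correlation), the pericentral list (adjusted p = 0.0415, median 0.11; adjusted p = 0.372 with an estimated correlation) and the acute phase list (adjusted p = 0.0484, median 0.09; adjusted p = 0.597 with an estimated correlation). All 4 calls were lost without array 2 of the pair (adjusted p = 0.143, 0.592, 0.478 and 0.467). The log2 ratios of the 2 arrays, turned to the same direction, had r = -0.347 across probes in this pair, against 0.0294 in the WT liver pair and 0.391 in the tumour pair, where probes are not independent replicates. These ratios still held the dye effect of each probe, which takes opposite signs on the 2 turned arrays and so lowers r. The fit removed that effect. The software's error model, applied to both arrays, called 77 probes higher and 14 lower, and the count of higher probes was 3 without array 1 of this pair and 6 without either tumour array.

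**Figure D1:**
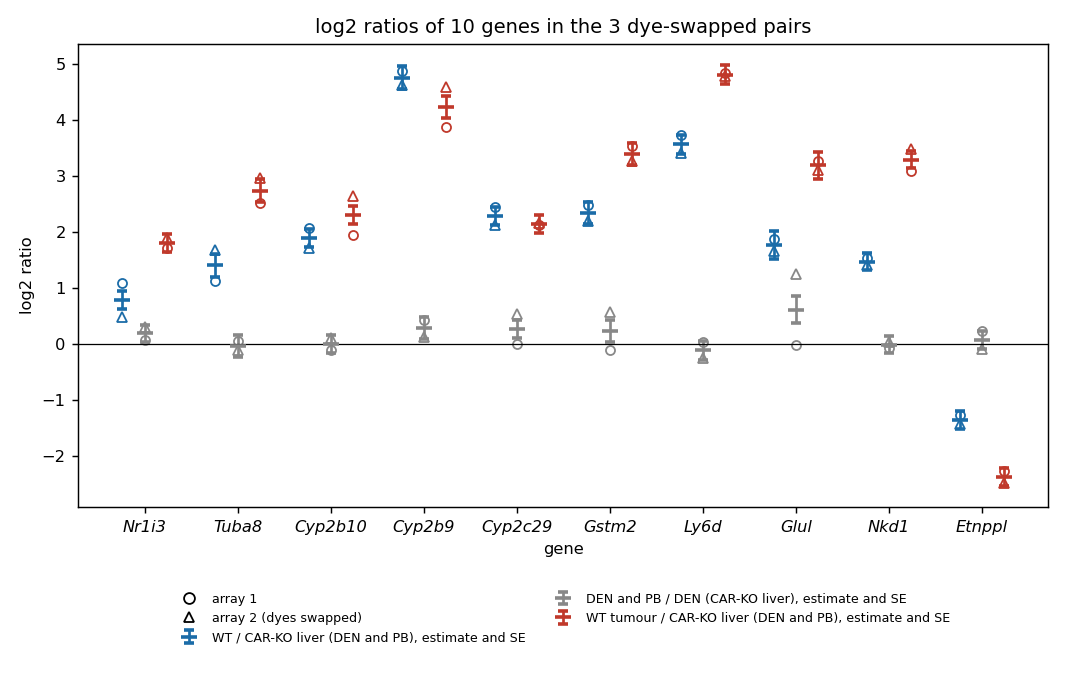
log2 ratios (vertical axis) of 10 genes in the 3 pairs, as limma estimate with SE (bars) and the 2 arrays (circle, array 1; triangle, array 2 with dyes swapped). Cyp2b9 stood at 4.76 and 4.24 against CAR-KO liver in WT liver and WT tumour and at 0.28 for PB in CAR-KO liver.

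The comparison of WT tumour with CAR-KO liver, both after DEN and PB, asked which genes were induced in tumours relative to liver without CAR. It differs in genotype and in tissue state at once, so it cannot separate them. The same P450 genes and Ly6d led the list, joined by genes of the pericentral zone. Ly6d was 28.2-fold higher (log2 ratio 4.82 ± 0.17, adjusted p = 9.1e-05), Cyp2b13 23.7-fold (4.56 ± 0.18), Cyp2b9 18.8-fold (4.24 ± 0.20), Pnliprp1 17.4-fold (4.12 ± 0.15), Nkd1 9.82-fold (3.30 ± 0.16) and Glul 9.17-fold (3.20 ± 0.24, adjusted p = 0.0011). Tuba8 was 6.70-fold higher (2.74 ± 0.20; 2.51 and 2.98 on the 2 arrays; adjusted p = 0.00105), and its adjusted p passed in 13 of 15 alternatives (1.05e-05 to 0.14).

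Of 11 measured tubulin genes 3 were higher, with Tubb6 (2.68 ± 0.17) and Tubb5 (1.01 ± 0.17) beside Tuba8. Of the 14 pericentral genes 10 were higher and all 14 ratios were positive (median 1.72), including Rhbg (3.24 ± 0.17) and the Wnt-responsive factor Sp5 (2.68 ± 0.19), while Axin2 (0.21 ± 0.16) did not pass. Of 7 periportal genes 5 were lower (median -1.63), among them Etnppl (-2.37 ± 0.16), Cyp2f2 (-2.05 ± 0.17), Pck1 (-1.79 ± 0.16) and arginase 1, Arg1 (-1.63 ± 0.31). Camera called the tubulin list (adjusted p = 0.00144) and the pericentral list higher (adjusted p = 2.59e-12) and the periportal list lower (adjusted p = 9.01e-07), each with an adjusted p = 0.259 with an estimated correlation.

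Of the 21 CAR and PB genes 15 were higher in WT tumour (median 1.66), including Cyp2c55 (3.58 ± 0.15) and Gstm2 (3.40 ± 0.19). Of 13 NRF2 antioxidant genes 7 were higher, among them Nqo1 (2.18 ± 0.16), Ugdh (2.11 ± 0.17), Gpx2 (1.77 ± 0.16) and Txnrd1 (1.18 ± 0.16), and the metallothionein Mt1 was lower (-0.99 ± 0.17). Camera called the CAR and PB list (adjusted p = 2.62e-20) and the NRF2 list higher (adjusted p = 2.47e-05), each with an adjusted p = 0.259 with an estimated correlation and an adjusted p = 0.0447 with fry.

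Genes of growth and sterol synthesis were higher in part. Of 15 tumour and fetal liver markers 7 were higher (median 0.92), including Scd2 (2.31 ± 0.22), Igfbp1 (2.07 ± 0.17) and the growth factor Igf2 (2.03 ± 0.19), while alpha-fetoprotein, Afp, had a ratio of 0.07 ± 0.15. Of 18 cell cycle genes 5 were higher (median 0.44), including Plk1 (1.24 ± 0.16), Mcm6 (1.18 ± 0.17), Rrm2 (1.14 ± 0.18) and Mcm4 (1.08 ± 0.16). Of 11 cholesterol synthesis genes 5 were higher and all 11 ratios were positive (median 0.68), including Sqle (1.07 ± 0.15), Nsdhl (1.03 ± 0.17), Fdps (1.02 ± 0.17) and Mvd (0.97 ± 0.18). Camera called the tumour marker list (adjusted p = 1.28e-06), the cell cycle list (adjusted p = 0.000248) and the cholesterol list higher (adjusted p = 3.36e-05), each with an adjusted p = 0.259 with an estimated correlation. Elovl6 (1.53 ± 0.16) and Gpam (1.04 ± 0.18) were the 2 called of 9 lipogenesis genes, and Gdf15 (1.02 ± 0.19) and Ccng1 (0.95 ± 0.17) the 2 called of 11 p53 targets. Camera called the lipogenesis list higher (adjusted p = 0.0142; adjusted p = 0.313 with an estimated correlation) and the p53 list higher (adjusted p = 0.00493; adjusted p = 0.287 with an estimated correlation), and both calls were lost without array 2 of the tumour pair (adjusted p = 0.0616 and 0.178).

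Of 11 genes of gluconeogenesis and amino acid catabolism 5 were lower in WT tumour (median -1.02), including Pck1, Got1 (-1.52 ± 0.19), Fbp1 (-1.31 ± 0.15) and Agxt (-1.05 ± 0.16). Of 8 male-biased liver genes 4 were lower, namely Hsd3b5 (-1.92 ± 0.17), Cyp7b1 (-1.60 ± 0.18), Nudt7 (-1.15 ± 0.18) and Elovl3 (-1.12 ± 0.15). Camera called both lists lower (adjusted p = 9.01e-07 and 7.72e-05), each with an adjusted p = 0.259 with an estimated correlation, and the male-biased call was lost with median centring (adjusted p = 0.0553). Of 9 female-biased genes 3 were higher, all of them P450 genes of drug and steroid metabolism (Cyp2b9, Cyp2b13 and Cyp2a4, 2.66 ± 0.32), and camera did not call the list (adjusted p = 0.0839). Of 15 acute phase genes Fgg (-1.35 ± 0.17), Saa2 (-0.90 ± 0.15) and Saa1 (-0.89 ± 0.17) were lower and Orm2 (0.88 ± 0.16) was higher, and camera did not call that list (adjusted p = 0.169). Camera called the acute phase list higher in WT over CAR-KO liver (adjusted p = 0.00137, or 0.418 with an estimated correlation and 0.124 with median centring). It called the list lower in WT tumour over WT liver (adjusted p = 0.00257, or 0.429 with an estimated correlation). Each had 0 members passing limma's test. Other large decreases in WT tumour over CAR-KO liver were Fut2 (-1.96 ± 0.18), Ces1e (-1.90 ± 0.18), the hepcidin gene Hamp (-1.90 ± 0.17), Olfr166 (-1.86 ± 0.18), Tnnc2 (-1.83 ± 0.15) and Mug1 (-1.71 ± 0.15).

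In total 524 probes were higher and 174 lower, of 20744 tested, and 4858 passed an unadjusted p under 0.05. Of these 328 and 105 changed at least 2-fold. Without array 2 of the tumour pair the counts were 1799 higher and 2909 lower, a higher share of 38.2% in place of 75.1%. They were 218 and 67 without either array of the PB pair and 318 and 100 without either array of the WT liver pair. Leaving out 1 or the other array of such a pair gave the same fit for WT tumour, with fewer residual degrees of freedom. They are therefore not separate checks. Of the genes named above, Gpam, Fdps, Mvd, Gdf15, Ccng1, Saa1, Saa2 and Orm2 missed the threshold when an array of either pair was left out. Sqle, Nsdhl, Agxt, Mcm6, Rrm2, Mcm4 and Tubb5 missed it without an array of the PB pair. Fdps, Ccng1, Tubb5 and Orm2 also missed it without array 1 of the tumour pair, and Gdf15 and Saa1 without array 2. Median centring in place of loess gave 2370 and 1763 (57.3% higher), and the signals processed by the Agilent software gave 0 and 0 (smallest adjusted p = 0.0803), with the sign of all 698 called probes kept in both.

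**Figure D2:**
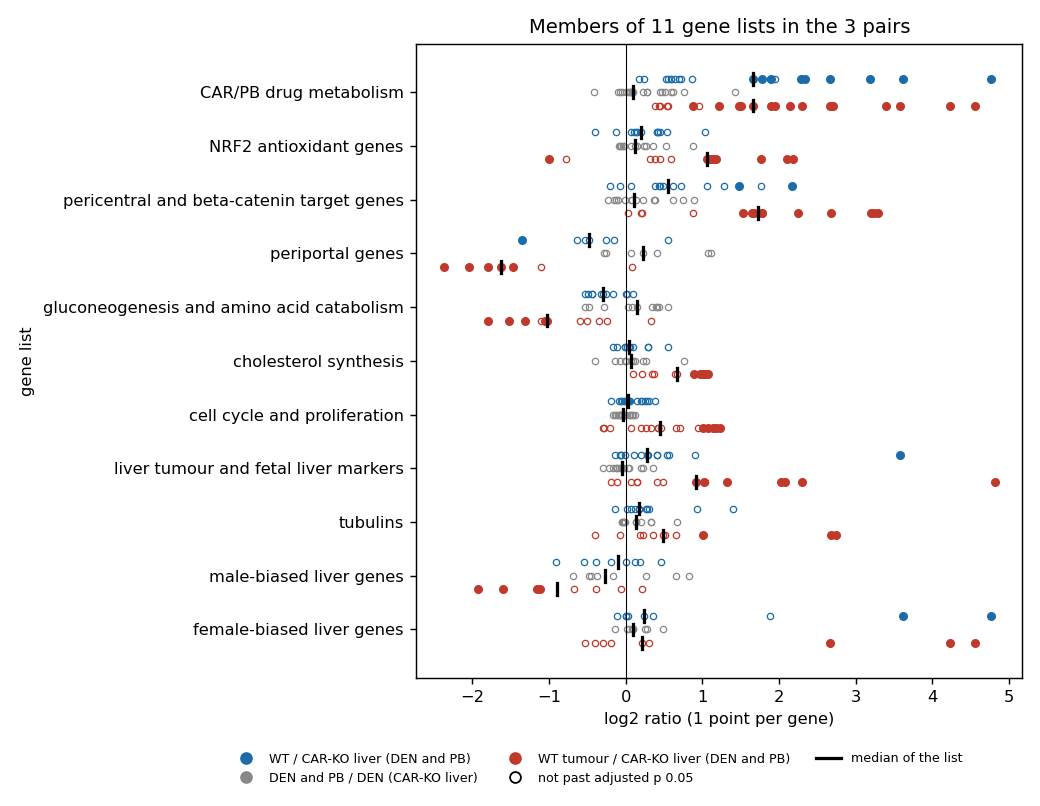
log2 ratios (horizontal axis) of the measured members of 11 gene lists in the 3 pairs, 1 point per gene, filled where the adjusted p passed 0.05, with the list median as a bar. The pericentral list had a median of 1.72 in WT tumour and 0.55 in WT liver, each against CAR-KO liver.

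The overlap of the WT liver and WT tumour comparisons was made for the study's first aim, genes that depend on CAR and are induced in tumours. Both comparisons are against CAR-KO liver. A gene that depends on CAR can thus enter the overlap without being induced in tumour over WT liver. All 19 probes higher in WT liver were also higher in WT tumour, 15 of them with a gene symbol, where independent lists share 0.48. The genes with the largest values in both were Cyp2b9 (4.76 in WT liver and 4.24 in WT tumour), Cyp2b13 (3.62 and 4.56), Ly6d (3.58 and 4.82), Cyp2c37 (3.19 and 2.70), Cyp2c55 (2.67 and 3.58), Cyp2c39 (2.75 and 2.60), Pnliprp1 (2.35 and 4.12), Gstm2 (2.34 and 3.40), Rhbg (2.17 and 3.24) and Cyp2c29 (2.29 and 2.14). In the indirect comparison of WT tumour with WT liver, where 0 probes passed, Cyp2b9 had -0.53, Cyp2c37 -0.485, Cyp2c29 -0.15 and Cyp2c39 -0.15. Cyp2b13 (0.95), Cyp2c55 (0.91), Gstm2 (1.06), Rhbg (1.08), Ly6d (1.24) and Pnliprp1 (1.77) had positive ratios there. Tnnc2 and Etnppl were the 2 probes lower in both WT liver and WT tumour than in CAR-KO liver, and 0 were called in opposite directions. For PB in CAR-KO liver 0 of all 20742 tested probes passed, so that 0 of the overlapping probes did says nothing particular about them. Tuba8 was not in the overlap, since its WT liver ratio missed the threshold.

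Both comparisons share CAR-KO liver, so differences of that sample alone make their ratios move together. In 20 simulations without sample differences the overlap was 0 and the correlation across probes averaged -0.00105, against 0.462 observed, where probes are not independent replicates. With sample differences of 0.5 times the array SD, only those of CAR-KO shared, the overlap averaged 5.45 probes with a highest of 13 and the correlation 0.25. The SD of the WT liver log2 ratios was 0.189 without and 0.266 with sample differences in these simulations, against 0.187 observed. Simulated array noise alone thus already reached the observed spread, which includes the large ratios of the called probes. That noise may be too wide for the WT liver pair, whose arrays had weights of 1.77 against 0.486 for the tumour arrays. The SD therefore cannot show whether sample differences of the simulated size were too large. The overlap was 4 without either WT liver array, 8 without either array of the PB pair, 67 and 71 without array 1 and array 2 of the tumour pair, and 0 on the signals processed by the Agilent software.

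**Figure D3:**
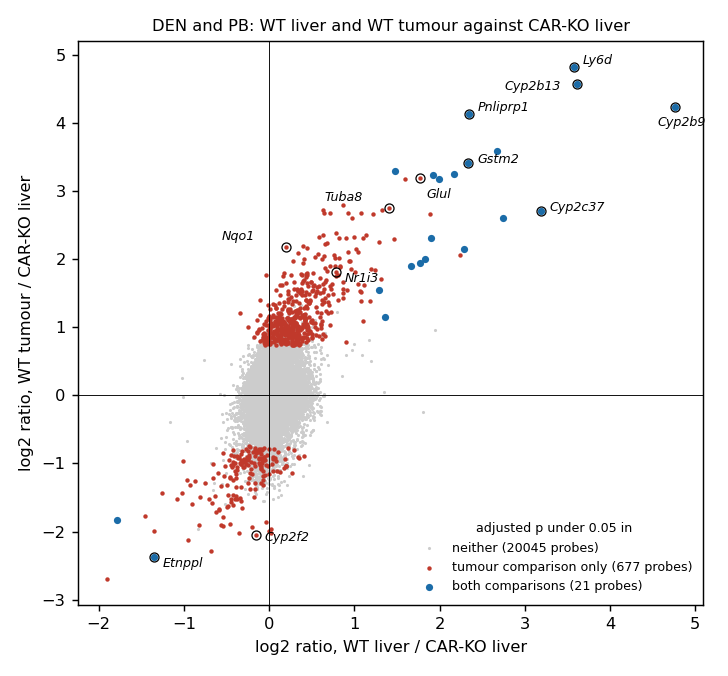
log2 ratio of WT liver over CAR-KO liver (horizontal axis) against WT tumour over CAR-KO liver (vertical axis), 1 point per probe, coloured by the comparisons in which the adjusted p passed 0.05. The 21 probes called in both lay on the same side of 0 in both comparisons.

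The indirect comparison of WT tumour with WT liver asked which genes differed between tumour and liver of the same genotype. Its estimates for Tuba8 (log2 ratio 1.34 ± 0.28, adjusted p = 0.314) and Nr1i3 (1.02 ± 0.23, adjusted p = 0.327) did not pass the test. The pericentral list had 14 of 14 positive ratios (median 1.13), 9 of them past the threshold when adjusted over the list alone, while the periportal list had 7 of 7 negative (median -1.02). Camera called the pericentral list higher (adjusted p = 8.1e-11) and the periportal list lower (adjusted p = 2.46e-07), each with an adjusted p = 0.259 with an estimated correlation. Camera also called the lists of tumour markers (adjusted p = 1.39e-05), cholesterol synthesis (1.96e-05), and cell cycle and NRF2 genes (0.000107 each) higher. Fatty acid oxidation (0.00536), tubulins (0.0149) and p53 targets (0.0167) were also called higher. Called lower, beside the acute phase list, were gluconeogenesis (4.74e-06), male-biased genes (4.48e-05) and erythroid markers (0.0115), all lost with median centring. None was called with an estimated correlation (0.259 to 0.429). The CAR and PB list had a median of 0.28, with 5 of 21 members past the threshold when adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.313 with an estimated correlation; adjusted p = 0.23 without array 1 of the tumour pair).

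With limma 0 probes were higher and 0 lower, 1737 passed an unadjusted p under 0.05, and the smallest adjusted p was 0.137. The median SE was 0.241, against 0.17 for the direct comparisons, and the CAR-KO term cancels only if its RNA was equivalent in both pairs. Without array 1 of the tumour pair 122 probes were higher and 72 lower, with Tuba8 at 1.75 (adjusted p = 0.0123). Without array 2 the counts were 426 and 1738, with Tuba8 at 0.93 (adjusted p = 0.0452) and Nr1i3 at 1.14 (adjusted p = 0.0183). Over all alternatives the adjusted p of Tuba8 ran from 0.0123 to 1, and its log2 ratio was -0.12 on the signals processed by the Agilent software, while the adjusted p of Nr1i3 ran from 0.0183 to 1.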

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

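The Agilent processed signals with dim probes left out, and median centring without loess and without a dye effect, were chosen after the data were seen; all other alternatives were planned. The cause was not tested for the counts below, except where the construction of the alternative shows it. Leaving out an array leaves 1 array in a pair, whose spread is then assumed to be that of the others. That array is fitted exactly, so leaving out 1 or the other array of a pair gives the same fit for comparisons without that pair. In every alternative fitted with limma, all called probes of WT liver and of WT tumour that had a value kept their sign. The largest move of the median log2 ratio of all probes was 0.103, for WT tumour against WT liver on the Agilent processed signals with dim probes left out, where fewer probes were tested.

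Counts are given as higher and lower. For WT against CAR-KO liver (19 and 2) the counts were 0 and 0 on the Agilent processed signals and on the deposited value table, 69 and 18 with only the arrays of the pair, 70 and 17 with array weights, 6 and 0 with the Agilent signals and dim probes left out, 7 and 0 with median centring without dye effect, and 329 and 67 with the Agilent error model, which sets no multiple-testing threshold. The lower count was 4 with median centring and without background subtraction, and 1 without dye effect or without the filter. Leaving out single arrays gave 4 to 76 and 0 to 18.

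For PB in CAR-KO liver (0 and 0) the higher count was 1 with the strict filter and with array weights, 77 with the Agilent error model (14 lower), and 0 to 6 leaving out single arrays. For WT tumour against CAR-KO liver (524 and 174) the counts were 2370 and 1763 with median centring, 0 and 0 on the Agilent processed signals and the deposited value table, 53 and 9 with only the arrays of the pair, 186 and 41 with array weights, 188 and 33 with the Agilent signals and dim probes left out, 320 and 18 with median centring without dye effect, 328 and 105 with the 2-fold threshold, which removes probes by construction, and 1607 and 674 with the Agilent error model. The lower count was 99 without dye effect. Leaving out single arrays gave 218 to 1799 and 67 to 2909, the upper ends without the array from the other scanner.

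For WT tumour against WT liver (0 and 0) median centring gave 47 higher, and leaving out single arrays gave 0 to 426 and 0 to 1738. The overlap of 19 probes became 0 on the Agilent processed signals and the deposited value table, 36 with only the arrays of the pair, 59 with array weights, 6 with the Agilent signals and dim probes left out, 7 with median centring without dye effect, 188 with the Agilent error model and 4 to 71 leaving out single arrays. Of the 108 list tests camera called 49, 0 with an estimated correlation and 3 with fry, which tests another hypothesis, and 41 to 55 leaving out single arrays. A list call changed direction in 3 cases, none past the threshold there: the acute phase list for PB in CAR-KO liver without array 2 of that pair (adjusted p = 0.467, with 0.0147 to 0.467 leaving out single arrays), and, with median centring, the hepatocyte list for WT tumour against CAR-KO liver (adjusted p = 0.24) and the acute phase list for WT tumour against WT liver (adjusted p = 0.538).

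Of 1250 alternative values for the 74 called results of named genes, 874 stayed past the threshold in the same direction, 376 kept the direction but missed the threshold, and 0 changed direction. For the 26 uncalled ones, 16 of 432 values passed the threshold. These tallies do not count separate checks, since the Agilent processed signals and the deposited value table hold nearly the same ratios. Leaving out 1 or the other array of a pair also gave the same fit for comparisons without that pair. Genes named for their largest changes had the same sign on both arrays by rule. A change of direction was thus unlikely when an array was left out. A batch term for the other scanner was not run, since its batch held 1 array. Signal over background limits dim probes such as that of Tuba8, whose ratio rests on the background correction.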

Other observations

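The tests of tumour RNA, of genes next to Nr1i3 and of muscle markers were set out before the values they measure were seen, except that the values of Apoa2 and Apcs near Nr1i3 and of 5 muscle genes had been seen, while the shares for probes lower in tumour, the second muscle probes, the other sets of muscle markers and the muscle probe descriptions were looked at afterwards.

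Few markers of other cell types passed the test in WT tumour. In WT tumour over CAR-KO liver the median log2 ratio was 0.25 over 9 macrophage and Kupffer cell markers, 0.11 over 11 lymphocyte markers, -0.05 over 8 neutrophil markers and -0.08 over 8 endothelial markers, with 0 members passing limma's adjusted p in each and 1 endothelial and 1 macrophage member passing when adjusted over the list alone. Of 9 cholangiocyte and progenitor markers the keratin Krt19 was higher (1.13 ± 0.17, adjusted p = 0.0135), with a median of -0.03 and a mean of 0.17. Of 7 stellate cell and fibroblast markers the proteoglycan gene Dcn was lower (-1.34 ± 0.20, adjusted p = 0.0159; median -0.13). Of 5 erythroid markers the globin genes Hba-a1 (-1.09 ± 0.16) and Hbb-bt (-0.99 ± 0.18) were lower, and camera called the list lower (adjusted p = 0.0383; adjusted p = 0.386 with an estimated correlation; adjusted p = 0.0986 without array 2 of the tumour pair). Of 8 hepatocyte markers 0 passed and 7 ratios were negative (median -0.29; camera adjusted p = 0.0238; adjusted p = 0.313 with an estimated correlation; adjusted p = 0.392 without array 2 of the tumour pair), a direction that turned with median centring (adjusted p = 0.24). Of 6 adipocyte markers 0 passed (median -0.30), and of 7 pancreatic acinar markers 0 passed (median -0.27).

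Of 18 genes of bile acid synthesis and transport Amacr was higher in WT tumour (0.76 ± 0.15, adjusted p = 0.0429) and Cyp7b1, of the alternative bile acid pathway, was lower (-1.60 ± 0.18), and the list's median was 0.03 against a mean of -0.13, with no camera call (adjusted p = 0.569). Of 13 genes of fatty acid oxidation the thioesterase Acot1 (1.21 ± 0.17) and Pdk4 (1.38 ± 0.18), a kinase that restrains pyruvate oxidation, were higher (median 0.08), and camera did not call the list there (adjusted p = 0.477). Camera called that list lower in WT over CAR-KO liver (adjusted p = 0.00134, median -0.17), a call lost on the Agilent processed signals (adjusted p = 0.0912). It called the list higher in WT tumour over WT liver (adjusted p = 0.00536, median 0.29). With an estimated correlation neither was called (adjusted p = 0.259 and 0.287), and each had 0 members passing limma's test. Of 10 interferon response genes Usp18 was higher (1.39 ± 0.17, adjusted p = 0.00623) and 9 ratios were positive (median 0.45; camera adjusted p = 0.00973; adjusted p = 0.313 with an estimated correlation; adjusted p = 0.115 without array 2 of the tumour pair).

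Pericentral and beta-catenin target genes leaned higher in WT liver as well as in WT tumour, and tumour RNA in the WT liver sample is a candidate explanation. If so, list members and other genes would show about the same share of the tumour's excess, and the ratio of the medians, others over list members, was 0.985 (95% bootstrap interval 0.488 to 1.37), with median shares of 19.1% over 514 probes and 19.4% over 10 list members; the interval reaches under the bound of 0.5, which the test as written set on the ratio alone. CAR and PB list members had a median share of 50.5%, so a mixture at that level could not account for all of theirs. Shares of single pericentral list members ran from 12% (Sp5) to 57.6% (Cyp1a2), with an SD of 15.2. The SD was 20.8 over the other probes called higher in tumour. The matching medians therefore do not show 1 share common to all genes, and how much of the spread is noise was not tested. Probes lower in tumour had a median share of 33.6%, and the shared CAR-KO side adds to every share, so early lesions in WT liver, an effect of CAR on these genes in liver and differences of the CAR-KO sample stay open. The labels name genotype and tissue but do not say whether WT liver was taken clear of tumours.

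Genes may also differ between WT and CAR-KO samples because a chromosome segment around the deleted Nr1i3 gene came from the strain in which it was deleted. Among 61 probes of the 200 genes next to Nr1i3, 4 were called in WT tumour over CAR-KO liver (Mgst3 with 2 probes, Pfdn2 and Uap1), or 6.56% against 4.48% of other named probes, an odds ratio of 1.5 (95% interval 0.392 to 4.07, Fisher's exact p = 0.353). In WT over CAR-KO liver 0 of the 61 were called by limma, against 17 of the other 9576. Too few probes lie near the gene to separate a segment effect from none. The P450 genes that lead both comparisons were not among the 61 probes, so the test says nothing about them.

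The 9 probes whose descriptions name skeletal muscle or myosin heavy chain and that were lower in WT tumour ran from -1.91 to -0.66 in WT over CAR-KO liver, where only Tnnc2 passed, and from 0.89 to 1.93 with PB in CAR-KO liver, where 0 passed limma's test, so skeletal muscle RNA in the CAR-KO sample after DEN and PB, which could enter at dissection, is a candidate source. Over 27 measured muscle markers not looked at before, the median in WT over CAR-KO liver was -0.048 (95% bootstrap interval -0.1 to 0.03), inside the bound set beforehand against it, with Ckm at 0.29, Mb at 0.25 and Atp2a1 at 0.03, all on probes dimmer than any of the 9, and the brighter Mylpf at -0.87, Tnni2 at -0.66 and Sln at -0.10, which was lower in WT tumour (-0.79) but at -0.26 with PB. The bound was also met with Tnnc2 and Myh2 put back (median -0.05, -0.105 to -0.001) and over the 22 markers brighter than the second probes of Myh2 and Mylpf (-0.083, -0.183 to -0.001), which stayed near 0 at -0.07 and -0.13, but not over the 16 at least as bright as the dimmest of the 9 probes (-0.083, -0.38 to -0.003). The 4 sets overlap, so 3 of them meeting the bound is not repeated evidence. The set held to probes as bright as the 9 did not meet it. The test therefore does not settle whether muscle RNA carrying all its abundant transcripts was present. A source rich in few of these transcripts and a rise in the liver also stay open. No biological explanation was tested.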
